A study of Homo sapiens with 7 samples.

How the data were processed

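RNA of isolated peripheral blood neutrophils from 7 healthy subjects was measured by RNA-seq, 1 library per subject. Per the labels' protocols, total RNA was extracted with a NucleoSpin RNA Plus kit, libraries were made with the Kapa stranded mRNA kit, which selects polyadenylated RNA, and sequenced as single-end 50 bp reads on an Illumina NovaSeq. Per the submitters' processing notes, Trim Galore, STAR and HTSeq were used for trimming, alignment and counting. Their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, 1 table per library, with no normalization. The summary row for reads aligned to several places is 0 in each complete table, and how such reads were treated before counting is not given in the sources used here, so the levels of genes with near-identical copies are treated as uncertain. Selection of polyadenylated RNA lowers non-polyadenylated transcripts such as replication-dependent histone mRNA.

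The complete tables held 58395 gene rows and summary rows for reads with no feature (8.29 to 21.1% of the gene, no-feature and ambiguous counts together) and ambiguous reads (2.67 to 3.15%). The other summary rows were 0. Summary rows were left out of library sizes and all measures. The table of sample 1 used here ended after 9627 usable genes and held no summary rows, and its final incomplete row was not used. The design fixed before the data were examined had all 7 samples in each measure. It could not be run that way, so the main values use the 6 complete libraries, and 3 departures were added after the data were seen: all 7 samples on the shared genes, the 6 complete samples on the same genes, and levels of sample 1 scaled on shared genes. Sample numbers follow the order of the deposited records and carry no meaning.

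Gene names came from a gene name table that matched 57754 of the 58395 IDs, and biotypes and coordinates from GENCODE release 29 on GRCh38, which matched 58275. Coordinates are those of that annotation. Genes on chromosome Y, XIST and related genes were left out of every ranking by spread, since their levels follow sex. So was a set of genes known for common inherited variation in level (HLA, KIR, GSTM1 and similar). Genes outside that set can carry such variation too, and the ranked genes were not checked for it. Genes on chromosome Y and XIST were also left out of list scores and, by a change made after the data were seen, of correlations between libraries and of the principal components. No sample's level of a sex-specific gene and no sequence variant was examined.

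Library sizes were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 (0.789 to 1.17), and counts were turned into CPM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest. A gene was detected at 1 CPM. The level of a list is the median CPM of its matched members in a library. The spread of a gene is the ratio of its second-highest to its second-lowest library, among genes with a median of at least 1 CPM. Taking the second values lessens the weight of a single extreme library but does not remove it, and the measure is a description with no replicates behind it. The same count was made on Poisson counts with 1 level per gene. A list score is the mean over members, with a median of at least 1 CPM, of log2(CPM + 1), each gene centred on its median over libraries. Its range from second-lowest to second-highest library was placed among 10000 random lists of the same size matched in 20 expression bins, and a list with at least 5 scored members was called at the 99th percentile. The 33 lists (neutrophil granules, receptors, oxidase, inflammasome, activation and interferon programmes, metabolism, markers of other blood cells, and reference sets) and the 14 relations between them were fixed before the data were examined. Correlations over 6 samples were tested by exact permutation.

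The genes named in the text follow a rule fixed before the data were examined. It takes the 20 genes with the highest median CPM, leaving out mitochondrially encoded and ribosomal protein genes. It takes the 24 protein-coding genes with a median of at least 5 CPM and the widest spread. From each list it takes the 2 members with the highest median CPM and, for called lists, the 3 with the widest spread. Some genes that the rule takes are not reported here. Genes named under the other observations were chosen after their values were seen.

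The measures were tested on simulated data. For the spread of genes, counts of 11450 genes were drawn from the means and sizes of the 6 complete libraries with a biological variation of 10% CV, and 200 genes were changed in 3 libraries, 100 per fold size. The count over 2-fold took 99% of genes changed 3-fold, 4% of genes changed 1.5-fold and 0% of unchanged genes. For the spread of lists, 0 of 100 random lists reached the 99th percentile, and a list shifted by 0.5 on the log2 scale was recovered with a range of 0.50 at the 100th percentile. The simulated genes varied independently of each other and by 10% CV only. The rates of false calls therefore do not carry over to the real libraries, where genes vary together and some more widely.

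Alternatives listed before the data were examined were DESeq2 1.42.0 size factors, total-count scaling, library sizes without mitochondrially encoded, ribosomal protein and haemoglobin genes, pseudocounts of 0.25 and 5, list scores by the median, a filter at 5 CPM or none, the full range between libraries, 50 expression bins, list means for levels, detection at 0.5 CPM or at 10 counts, and leaving out each sample. The complete libraries held 38808134 to 48306013 gene reads. At these depths 3 counts correspond to 0.0586 to 0.0918 CPM.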

Results

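The data consisted of RNA-seq read counts for neutrophils isolated from the peripheral blood of healthy subjects, the short-lived granulocytes that take up microbes and release granule proteins and reactive oxygen. The title of the series and its design text name a "low" and a "high" neutrophil activation phenotype, with 4 and 3 subjects. The labels used here do not say which of the 7 libraries belongs to which phenotype. All 7 libraries are therefore unassigned, they are called samples 1 to 7, and no comparison between phenotypes was made. Each value below is given per sample, or as the median and range over samples, and describes which programmes the cells expressed and which genes differed between libraries.

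The 6 complete libraries, samples 2 to 7, held 44867468, 38808134, 41431862, 48306013, 44960317 and 43325210 reads counted on genes. The table of sample 1 used here covered 9627 of the 58395 genes, with 21711984 reads on them, against 20751408 to 27920125 reads on the same genes in the other libraries. Sample 1 is therefore given only for genes it covers, and all medians and ranges refer to samples 2 to 7 unless stated. A median of 11433 genes (range 10152 to 11975) reached a CPM (read counts scaled by library size) of 1 in a library. The limit that 3 counts set was 0.0586 to 0.0918 CPM, so a gene with no read in a library may have been present at up to that level. Limits and intervals cover counting error only, since the reads carried no molecular identifiers.

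Transcripts of mature neutrophils filled the libraries. The 20 genes of the mature neutrophil identity list had a median level of 1261 CPM (973 to 1909), and all 20 had a median of at least 1 CPM. S100A9, a calcium-binding protein of the neutrophil cytosol (chromosome 1, 153357854 to 153361027, GRCh38), stood at 9454 CPM (7232 to 17313), and its partner S100A8 at 4579 CPM (2655 to 6375). FCGR3B, the low-affinity IgG receptor of neutrophils (chromosome 1, 161623196 to 161631963), stood at 5641 CPM (3474 to 8435), with the reservation that its reads can be shared with its near-identical paralogue FCGR3A. CSF3R, the receptor of granulocyte colony-stimulating factor, stood at 4749 CPM (3928 to 6454), and MNDA, a nuclear antigen of myeloid cells, at 4364 CPM (2730 to 6744). Among the 20 most abundant genes were also B2M at 12668 CPM (8880 to 17547), ACTB at 10093 CPM, the long non-coding RNA MALAT1 at 5470 CPM (3560 to 7775), and SOD2, the mitochondrial superoxide dismutase, at 3849 CPM (1605 to 7750).

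By list median, programmes of the mature cell stood far above those of its precursors. Chemoattractant receptors had a list level of 565 CPM (327 to 893), led by CXCR2, a receptor of CXCL8, at 3818 CPM (2186 to 7660) and the formyl peptide receptor FPR1 at 2238 CPM (1568 to 3904). Genes of gelatinase granules and secretory vesicles stood at 552 CPM (471 to 708), and adhesion and activation surface molecules at 287 CPM (216 to 422). The NADPH oxidase, the source of the oxidative burst, stood at 372 CPM (326 to 482), with RAC2 at 910 CPM (716 to 1363). Levels were lower for Toll-like receptor signalling (83.6 CPM, 61.8 to 121), inflammasome genes (53.5 CPM, 37.4 to 95.6), leukotriene and prostaglandin synthesis (48.8 CPM, 25.7 to 69.2) and neutrophil extracellular trap genes (33.2 CPM, 27.3 to 37.8). The granule proteins made early in the marrow were lower again, at 12.5 CPM (5.51 to 26.3) for specific granules and 6.39 CPM (3.11 to 16.7) for azurophil granules. By list means the azurophil list stood at 146 CPM, next to 145 CPM for inflammasome genes, and LYZ alone, which encodes lysozyme, at 1548 CPM (427 to 2435). Genes of cycling cells and precursors stood at 1.11 CPM (0.99 to 1.42), and 8 of the 16 had a median of at least 1 CPM.

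Activation programmes were measurable in each complete library without any stimulation named in the labels. Immediate early genes stood at 67.7 CPM (44.5 to 204), with 24 of 25 at a median of at least 1 CPM, and DUSP1, a phosphatase that limits MAP kinase signalling, reached 3748 CPM (3272 to 6323). NF-kB inflammatory response genes stood at 71.5 CPM (41.4 to 108), with 22 of 27 matched members at a median of at least 1 CPM. CXCL8, the main neutrophil chemokine, was at 1374 CPM (552 to 2314) and PTGS2, the inducible cyclooxygenase, at 922 CPM (448 to 1227). Type I interferon genes stood at 37.4 CPM (21.1 to 90.2) and type II interferon genes at 61.9 CPM (34.3 to 77.5). Apoptosis and survival genes had a level of 79.6 CPM (59.2 to 81.3), with MCL1, the survival factor on which neutrophils depend, at 3807 CPM (2629 to 4432). Glycolysis genes stood at 106 CPM (92.3 to 146), hypoxia genes at 42.8 CPM (35.0 to 62.1), and heat shock and stress genes at 54.6 CPM (41.1 to 58.8).

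**Figure D1:**
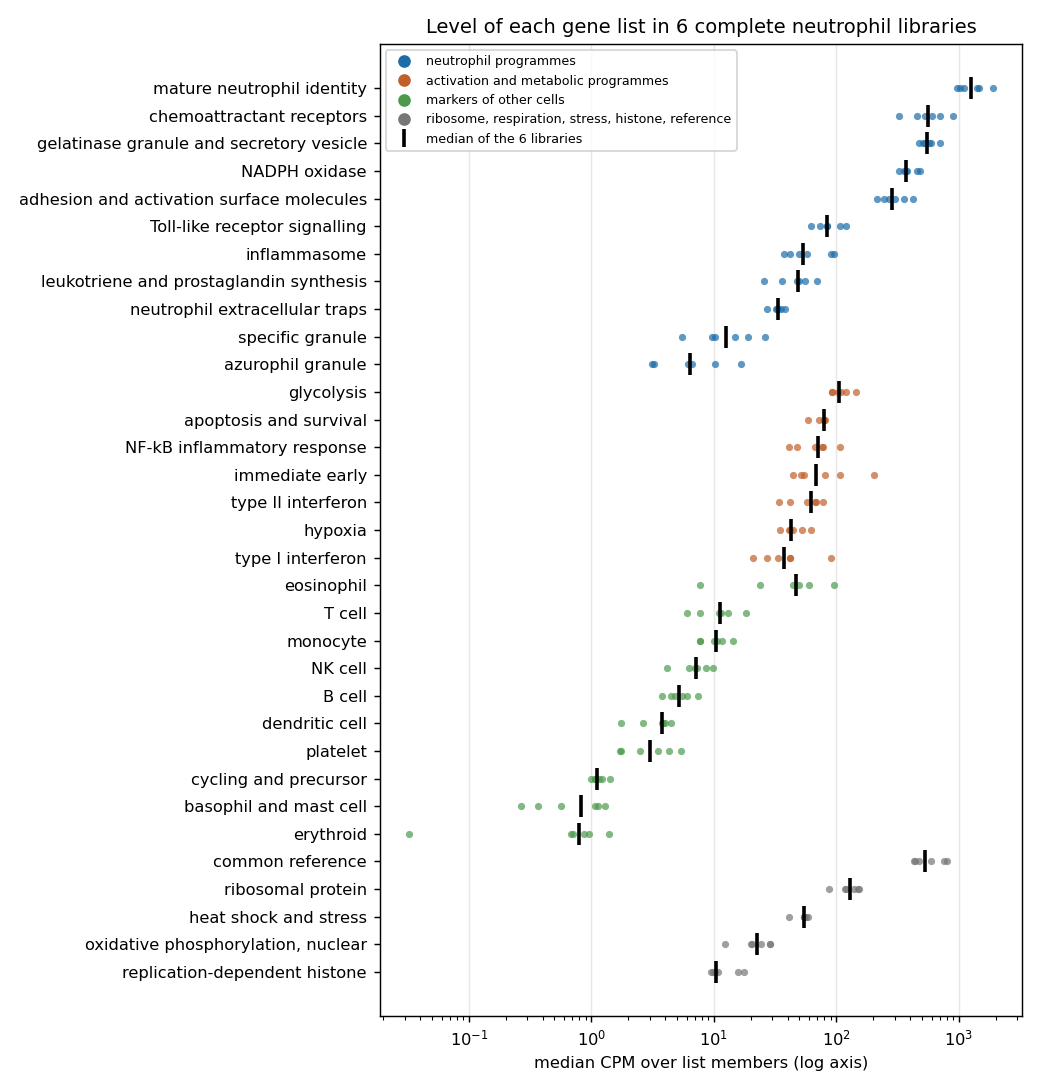
Median CPM over the members of each gene list (log axis), with 1 point per complete library (samples 2 to 7) and a bar at the median of the 6 libraries, coloured by class of list. The mature neutrophil identity list sits highest at 1261 CPM, and among the markers of other cells the eosinophil list sits highest at 46.9 CPM.

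Markers of other blood cells were low next to those of neutrophils, with eosinophils the exception. The eosinophil list stood at 46.9 CPM (7.71 to 95.8), with CLC, the Charcot-Leyden crystal protein (chromosome 19, 39731250 to 39738028), at 421 CPM (92.1 to 964). By list median, the mature neutrophil list was 26.9 times the eosinophil list, the highest of the lists of other cells. By list means the erythroid list was higher, at 138 CPM against 101 CPM for eosinophils. T cell genes stood at 11.1 CPM (6.0 to 18.2), monocyte genes at 10.4 CPM (7.66 to 14.3), NK cell genes at 7.16 CPM (4.18 to 9.92) and B cell genes at 5.17 CPM (3.76 to 7.38). Dendritic cell genes stood at 3.79 CPM (1.74 to 4.49), platelet genes at 3.02 CPM (1.72 to 5.40), basophil and mast cell genes at 0.82 CPM (0.26 to 1.30) and erythroid genes at 0.79 CPM (0.03 to 1.39). Within the erythroid list the haemoglobin genes were abundant in 5 of the 6 libraries, HBB ranging from 1777 to 3739 CPM there against 50.2 CPM in sample 2. Haemoglobin took 0.00770% of the reads of sample 2 (95% Wilson interval 0.00745 to 0.00796%) and 0.192 to 0.543% in the other complete libraries.

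Library composition differed between samples. Mitochondrially encoded transcripts took 7.24% of the gene reads in sample 3 (95% Wilson interval 7.23 to 7.25%) and 1.92 to 2.83% in the other complete libraries. Reads outside annotated features were 21.1% of the counted and uncounted reads in sample 3 and 8.29% in sample 4, with 10.9, 17.0, 15.8 and 13.1% in samples 2, 5, 6 and 7. Pearson's r of log2(CPM + 1) across genes lay between 0.951 and 0.983 over the 15 pairs of complete libraries, with a median of 0.972. No pair of libraries was a duplicate, since chi-square per gene was 93.7 at its lowest. The first principal component held 41.0% of the variance and set sample 4 (47.4) opposite sample 3 (-38.9), with the others between -8.90 and 10.2.

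A minority of genes varied widely between the libraries. Of 11199 genes with a median of at least 1 CPM, 1200 (10.7%) had a second-highest library more than 2-fold above the second-lowest, and 3872 (34.6%) exceeded 1.5-fold. The median ratio was 1.37. Poisson counts drawn with 1 common level per gene at the real library sizes gave 0 genes over 2-fold in each of 20 draws and at most 14 over 1.5-fold, so counting error alone does not give this spread. The count fell to 501 when sample 4 was left out and stayed under 708 when sample 2, 3, 5 or 7 was left out, against 888 without sample 6. Leaving out a sample narrows this measure by construction.

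The widest spread among protein-coding genes with a median of at least 5 CPM was that of TMTC1, a transmembrane mannosyltransferase (chromosome 12, 29500840 to 29784759), at 0.23 to 32.2 CPM with a ratio of second-highest to second-lowest of 82.9. CLEC4C, a C-type lectin receptor (chromosome 12, 7729415 to 7751605), followed with 0.51 to 28.2 CPM and a ratio of 52.5, and BTNL3, a butyrophilin-like gene, with a ratio of 42.5. BTNL3 stood at 0 and 0.54 CPM in samples 5 and 7 against 17.6 to 35.3 CPM in the other complete libraries. Inherited variation was not examined as a source. More abundant genes of this kind included S100P, a calcium-binding protein (chromosome 4, 6693069 to 6697170), at 25.6 to 488 CPM with a ratio of 12.6, and CLEC12A, an inhibitory lectin receptor of myeloid cells (chromosome 12, 9951316 to 9995694), at 10.6 to 376 CPM with a ratio of 11.3. IFITM3, an interferon-induced restriction factor for enveloped viruses (chromosome 11, 319669 to 327537), spanned 40.9 to 966 CPM with a ratio of 10.1, and stood at 1219 CPM in sample 1. ALPL, the alkaline phosphatase of secretory vesicles (chromosome 1, 21509372 to 21578412), spanned 258 to 2213 CPM with a ratio of 5.93. CD177, a surface glycoprotein known to be carried by a variable share of neutrophils, spanned 0.59 to 31.2 CPM, and CFD, which encodes complement factor D, 13 to 252 CPM. Other genes of this group were U2AF1L5, NFXL1, MXRA7, PAM, FOSB, MAST4, FGFR2, FADS2, SLPI, RNASE3, FOLR3, RNASE6, RNASE2 and CYP4F12, with ratios of 5.01 to 10.3. Overlapping annotated genes on the same strand (IFITM3, TMTC1, MXRA7, MAST4, FADS2, FOLR3) and close paralogues (U2AF1L5, RNASE2 with RNASE3) make the read assignment of these genes uncertain. The spread of BTNL3 fell under 2-fold without sample 5 (log2 ratio 0.38) or sample 7 (0.40), and that of CLEC12A without sample 5 (0.95) or sample 6 (0.95). The same held for FGFR2 without sample 4 (0.35) or 7 (0.37), FADS2 without sample 4 (0.20) or 7 (0.21), RNASE2 without sample 2 or 7 (0.78), RNASE3 without sample 2 or 7 (0.71) and RNASE6 without sample 5 (1.0). The log2 ratio of TMTC1 fell from 6.37 to 1.30 without sample 3 or 5, that of CLEC4C from 5.71 to 1.62 without sample 3 or 4, and that of S100P from 3.65 to 1.33 without sample 4 and 1.31 without sample 7. IFITM3 fell from 3.33 to 1.91 without sample 2 or 5, and ALPL from 2.57 to 1.14 without sample 4 or 7. The size of the spread of these genes therefore depends on the libraries included. A gene low or high in only 2 libraries narrows by construction when either is left out. These falls thus do not show that 1 library carries the spread. TMTC1 was low in samples 3 (0.24 CPM) and 5 (0.23 CPM), and stood at 0.18 CPM in sample 1. FADS2 was low in samples 4 (2.14 CPM) and 7 (5.29 CPM), with 2.16 CPM in sample 1. FGFR2, low in samples 4 and 7, had 6.05 CPM in sample 1.

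**Figure D2:**
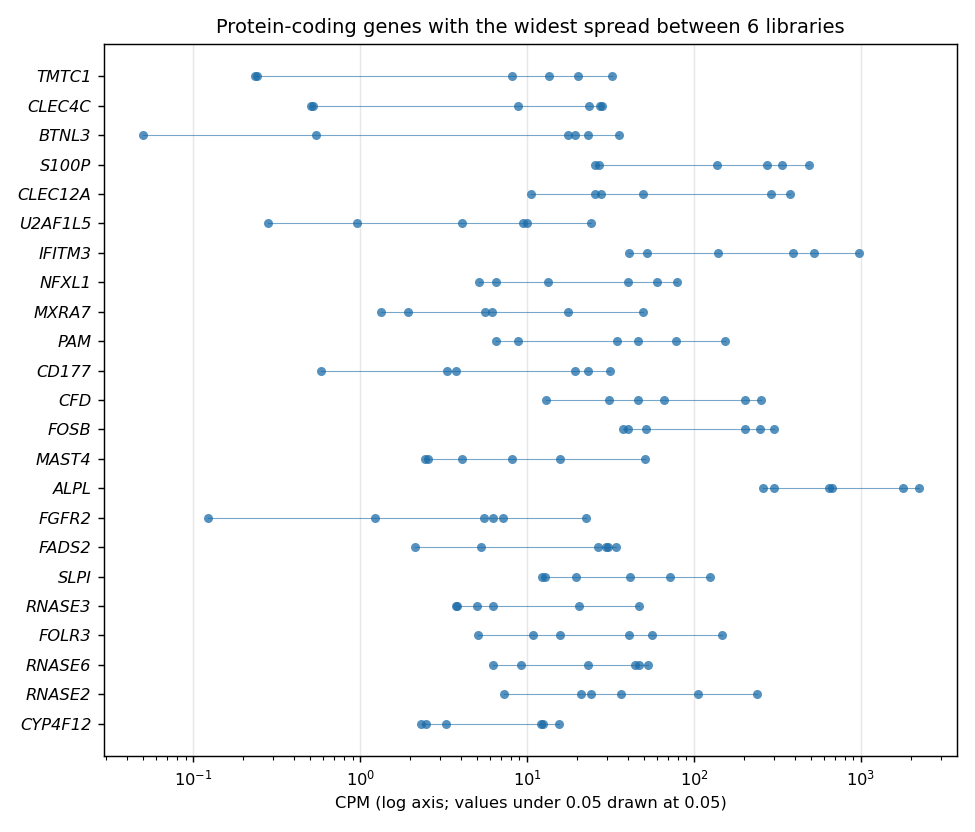
CPM (log axis) of 23 of the 24 protein-coding genes with the widest spread, with 1 point per complete library (samples 2 to 7) and a line from the lowest to the highest. Points of S100P run from 25.6 to 488 CPM and those of IFITM3 from 40.9 to 966 CPM.

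Gene lists were then asked whether their members moved together between libraries by more than random lists of like expression. Of 33 lists, 19 had a range between the second-lowest and second-highest library at or above the 99th percentile of 10000 random lists. By chance 0.33 lists would be reached if members varied independently of each other, as in the random lists. Members of a list picked for a common function can vary together, and some lists share members. The 0.33 is therefore not the number to be met by lists of this kind. The eosinophil list had the largest range, 1.27 on the log2 scale or 2.41-fold. Next came the immediate early list (0.85), the azurophil granule list (0.85), the platelet list (0.84), the specific granule list (0.78), the NF-kB list (0.78) and the type I interferon list (0.74), all at the 100th percentile. These ranges and their order depend on the libraries included, and leaving 1 out mostly narrows a range by construction. The eosinophil range fell to 0.58 without sample 5, 0.59 without sample 4, 0.70 without sample 3 and 0.71 without sample 2. Without sample 3, 4 or 5 the immediate early or the platelet list was wider, and other lists could be too. The azurophil list had 0.87 without sample 4 and 0.81 without sample 5, and the NF-kB list 0.79 and 0.78. The azurophil range fell to 0.29 without sample 2 and 0.31 without sample 3, the type I interferon range to 0.21 without sample 2 or 6, the platelet range to 0.49 without sample 7 and 0.50 without sample 4 and the specific granule range to 0.50 without sample 2. With all 7 samples on the shared genes, type I interferon (1.64), specific granule (1.59) and azurophil granule (1.5) ranges exceeded that of eosinophils (1.24). Random lists had a median range of 1.08- to 1.17-fold. The percentile describes these libraries and is not a p-value for subjects.

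Type I interferon genes, the antiviral programme induced by interferon alpha and beta, were highest in sample 6. Its score of 1.54 on the log2 scale was followed by 0.42 in sample 2, with the other 4 complete libraries between -0.44 and -0.12. All 25 scored members were highest in sample 6, and 13 of them by more than 2-fold over the next library. The erythroid list was also highest in sample 6 (0.63, with 6 of 9 scored members highest there). OAS3, a sensor of double-stranded RNA (chromosome 12, 112938352 to 112973249), stood at 253 CPM in sample 6 and 22.0 to 62.7 CPM in the other complete libraries, and at 231 CPM in sample 1. IFIT2 reached 981 CPM in sample 6 (252 CPM at the lowest) and 1143 CPM in sample 1. On the 19 members that sample 1 covers, its score was 1.17, against 1.52 in sample 6 and 0.31 in sample 2. The list dropped below the 99th percentile without sample 6 (95.8) or sample 2 (96.4). Type II interferon genes had a smaller range of 0.39 (99.9th percentile), with FCGR1A at 5.33 to 68.3 CPM and CD274, which encodes PD-L1, at 5.26 to 44.8 CPM, both highest in sample 7, and the list fell below without sample 6 (89.4) or sample 7 (94.3), or when scored by the median (98.3).

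Granule protein genes differed along another order of samples. Specific granule genes scored 0.70 in sample 2 and 0.52 in sample 3 and were lowest in sample 7 (-0.76), where 11 of the 15 members had their lowest level. LTF, which encodes lactoferrin (chromosome 3, 46435645 to 46485234), ranged from 28.6 CPM in sample 7 to 263 CPM in sample 2 and stood at 11.3 CPM in sample 1. LCN2 ranged from 5.51 to 41.5 CPM, MMP8 from 4.77 to 26.3 CPM and CHI3L1 from 88.9 to 841 CPM. Azurophil granule genes scored 0.82 in sample 2 and 0.54 in sample 3, and the other complete libraries lay between -0.41 and -0.03. The defensin DEFA3 ranged from 4.13 to 50.8 CPM, with reads that its near-identical copies can share, while RNASE2 (7.22 to 240 CPM) and RNASE3 (3.73 to 46.5 CPM) were highest in sample 7. The azurophil list fell below the 99th percentile without sample 2 (97.3) or sample 3 (98.9), whereas the specific granule list stayed at or above 99.97 under each of the 16 alternatives. Samples 2 and 3 also scored highest on the eosinophil list, and RNASE2 and RNASE3 are known as eosinophil granule proteins too. In sample 3, the highest on that list, they stood at only 24.2 and 5.04 CPM. The cycling and precursor list, below the 99th percentile, was also highest in these libraries (0.30 in sample 2 and 0.49 in sample 3).

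Genes of acute activation were highest in sample 7, for NF-kB genes only narrowly over sample 6. The immediate early list scored 0.79 in sample 7 and -0.63 in sample 2, and 17 of its 24 scored members had their highest level in sample 7. FOSB, a subunit of the AP-1 transcription factor, ranged from 37.5 to 301 CPM and EGR1 from 19.3 to 204 CPM, both highest in sample 7. The NF-kB list scored 0.47 in sample 7, 0.42 in sample 6 and -0.58 in sample 2, with 12 of 22 scored members highest in sample 7 and 12 lowest in sample 2. Total-count scaling moved all genes by 0.08 (log2) in sample 6 and -0.10 in sample 7. The order of samples 6 and 7 on the NF-kB list therefore depends on the scaling. NFKBIZ, an inducible regulator of NF-kB targets, ranged from 66.7 to 270 CPM, CCL3 from 2.26 to 8.87 CPM and CCL4 from 4.47 to 15.4 CPM. Of the scored NF-kB members 2 went the other way and were lowest in sample 7, CXCL8 among them. Inflammasome genes also scored highest in sample 7 (0.62), with AIM2, a sensor of cytosolic DNA, at 5.40 to 39.7 CPM and CASP5 at 9.71 to 93.0 CPM. The NF-kB and immediate early lists stayed at or above the 99.9th percentile under each of the 16 alternatives, but the NF-kB range fell from 0.78 to 0.40 without sample 6 or 7 and the immediate early range from 0.85 to 0.54 without sample 5 and 0.56 without sample 2, while the inflammasome list was lost under total-count scaling (90.7) and without sample 7 (98.7). Sample 7 also scored highest on the platelet list (0.53) and the T cell list (0.52).

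Eosinophil genes had the widest range of any list over the 6 complete libraries. The score was 1.08 in sample 3, 0.56 in sample 2 and -1.85 in sample 4, and 14 of the 16 scored members were highest in sample 3 and 14 lowest in sample 4. CLC ranged from 92.1 to 964 CPM, PRSS33 from 12.7 to 119 CPM and OLIG2 from 3.03 to 31.3 CPM. Samples 3 and 4 were also the libraries with the highest and lowest share of reads outside annotated features and those at the ends of the first principal component. The list stood at the 100th percentile under each of the 16 alternatives, a measure that is at its ceiling and does not show the fall in its range without sample 2, 3, 4 or 5. The mature neutrophil identity list ran the other way, at 0.57 in sample 4 and -0.28 in sample 3, while the monocyte list (0.37) and the mitochondrially encoded share (7.24%) were also highest in sample 3. Common reference genes (0.31 and -0.18) and chemoattractant receptors (0.30 and -0.32) ran as the neutrophil list did. Neutrophil extracellular trap genes did not (-0.10 and 0.12). Total-count scaling moved all genes by -0.34 (log2) in sample 4 and 0.23 in sample 3, which narrows the contrast of the neutrophil list.

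Other called lists were those of other cells and of basic processes. Platelet genes ranged over 0.84 and lost their call with total-count scaling (90.8), with TUBB1 at 15 to 39.7 CPM. T cell genes ranged over 0.58 (99.98th percentile), NK cell genes over 0.56 (99.9th) and monocyte genes over 0.37 (99.1st), with CD8A at 7.07 to 39.4 CPM and GZMH at 2.60 to 24.4 CPM. Adhesion molecules (0.51), histones (0.57), Toll-like receptor signalling (0.48), mature neutrophil identity (0.50), hypoxia (0.40), ribosomal proteins (0.39) and nuclear oxidative phosphorylation genes (0.39) also reached the 99th percentile. TLR5, the flagellin receptor, spanned 16.2 to 94.1 CPM and TLR2 190 to 722 CPM. Except for the platelet list, the calls of these lists were lost without 1 library or another, and some were also lost under another scaling or another choice. Total-count scaling ended those of Toll-like receptors (91.0), NK cells (90.9), hypoxia (87.5), histones (92.8) and monocytes (98.4), and DESeq2 size factors those of monocytes (98.9) and ribosomal proteins (98.8). Scoring by the median ended those of adhesion (84.8), Toll-like receptors (96.4) and hypoxia (98.7), and the filter at 5 CPM that of histones (80.4). The lowest percentile with 1 sample left out (not over all alternatives) was 35.8 for monocytes (without sample 5), 61.2 for mature neutrophil identity (sample 7), 89.1 for ribosomal proteins (sample 2), 89.1 for hypoxia (sample 2), 93.0 for oxidative phosphorylation (sample 6), 95 for NK cells (sample 7), 96.4 for Toll-like receptors (sample 7), 96.9 for T cells (sample 7), 98.1 for histones (sample 3) and 98.3 for adhesion (sample 5).

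The remaining 14 lists lay below the 99th percentile in the main setting. The percentiles were 98.6 for cycling and precursor genes, 98.1 for B cells, 97.8 for erythroid genes, 97.5 for common reference genes, 97.0 for chemoattractant receptors and 95.7 for gelatinase granules and secretory vesicles. Apoptosis and survival stood at 82.1, heat shock and stress at 76.2, dendritic cells at 69.4, glycolysis at 63.9, neutrophil extracellular traps at 54.8, NADPH oxidase at 42.6, leukotriene and prostaglandin synthesis at 28.2, and basophils and mast cells at 19.7. Under some alternatives 5 of these lists reached the 99th percentile: erythroid genes in 6 of 15, cycling and precursor genes in 4 of 15, B cells in 3 of 16, and glycolysis and chemoattractant receptors in 1 of 16 each. The NADPH oxidase list varied no more than random lists over the 6 complete libraries, with a range of 1.15-fold. On the genes shared with sample 1 its log2 range was 0.15 (25.4th percentile) in 6 samples and 0.52 (93.2nd) in all 7.

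**Figure D3:**
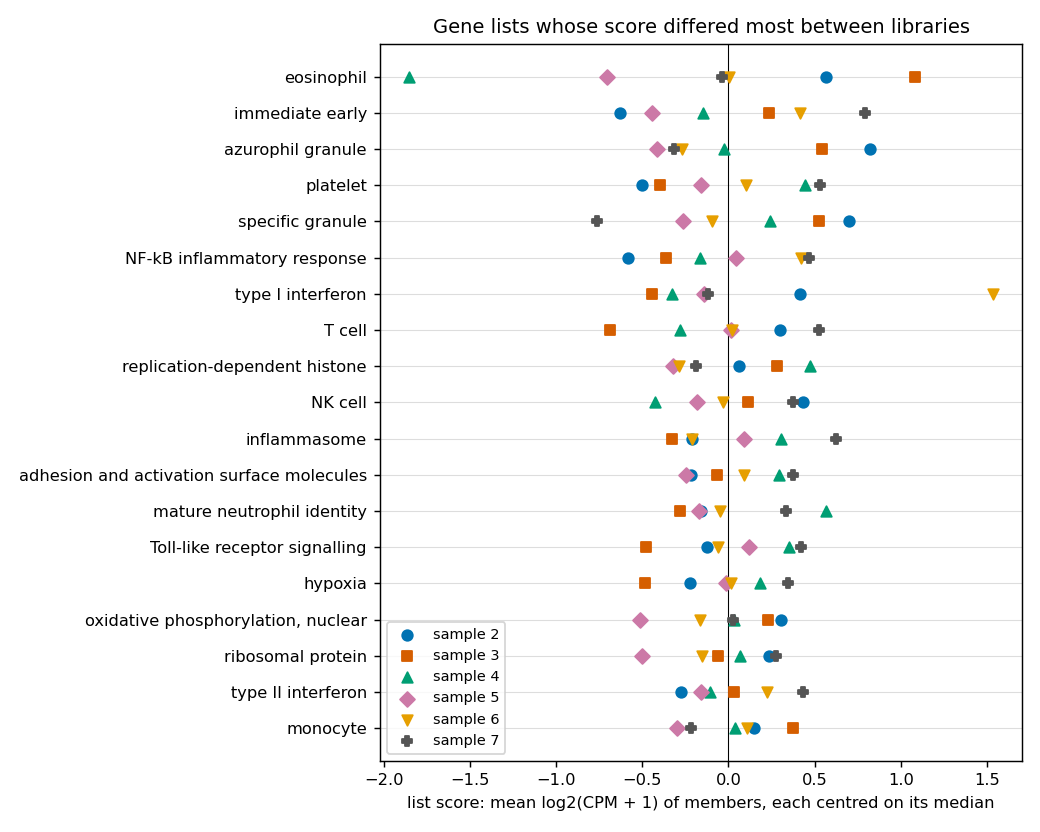
Score of each of the 19 gene lists at or above the 99th percentile (mean log2(CPM + 1) of members, each centred on its median), with 1 symbol per complete library (samples 2 to 7). The eosinophil list runs from -1.85 in sample 4 to 1.08 in sample 3, and sample 6 stands at 1.54 on the type I interferon list.

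Relations between lists were tested over the 6 complete libraries for 14 pairs of lists, with exact two-sided permutation tests over all 720 pairings and Benjamini-Hochberg adjustment over the 14. Azurophil and specific granule scores were the closest, with Pearson's r = 0.878 (exact p = 0.0167, adjusted p = 0.233) and Spearman's rho = 0.943 (exact p = 0.0167, adjusted p = 0.233), and r = 0.687 without the 2 samples farthest from the median. NF-kB and immediate early scores had r = 0.736 (exact p = 0.108, adjusted p = 0.671) and rho = 0.771 (exact p = 0.103, adjusted p = 0.622). Without the 2 farthest samples r was 0.249, and with 1 sample left out it was 0.571 to 0.888. Across the 13 relations other than the granule pair, r ran from -0.559 to 0.736 and no adjusted p of the exact Pearson test was below 0.671, nor of the exact Spearman test below 0.622. In total 0 of the 14 relations passed an adjusted 0.05 and 1 had an unadjusted exact p below 0.05 by the permutation test. The smallest exact p that 6 samples allow is 0.00278. The granule relation passed under total-count scaling (r = 0.903, exact test, adjusted p = 0.0194) and with lists scored by their median (r = 0.982, exact test, adjusted p = 0.0194), with adjusted p from 0.0194 to 0.831 (without sample 2) over the alternatives. The labels used here name no sequencing batch, so no relation was recomputed within batches.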

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

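Tests of reads outside annotated features, of depth (in place of 3 earlier forms whose outcome was fixed by how they were built), of eosinophils in the preparation and of other cells as a source of interferon genes were chosen after the results were seen, and the tests of transcript length and GC content, of scaling and of the number of genes behind a list were written down before. Apart from other cells in the preparations, no biological explanation was tested for any pattern, since the labels put no sample in a group.

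Among 66 measures over the 6 complete libraries, 2 had a library standing far from the rest, where about 3.3 would by chance. The mitochondrially encoded share was 7.24% in sample 3, and the gap to the nearest library was 0.830 of the whole range, above the critical value of Dixon's test at the 95% level. The erythroid list score was -2.08 in sample 2, with a gap of 0.738 of the range, and HBB and HBA2 stood at 50.2 and 23.4 CPM there.

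The first principal component set sample 4 apart from sample 3. A trend on transcript length or GC content was argued against as the whole source, since 0.972 of the difference stayed after such trends were taken out of each library, over the 99.9% of genes with a value. Reads outside annotated features remain open as a candidate explanation: their share followed the component with Pearson's r = -0.865 (exact permutation p = 0.0306, adjusted p = 0.0854 over 3 measures) and Spearman's rho = -0.714 (exact p = 0.136), but r was -0.172 without the 2 farthest samples. Such reads could follow pre-mRNA or DNA in the extract as well as the state of the cells, and 6 libraries do not separate these. The long intergenic non-coding share had Pearson's r = -0.774 (exact permutation p = 0.0569, adjusted p = 0.0854), but -0.0583 without its 2 farthest samples. The mitochondrially encoded share had r = -0.621 (exact permutation p = 0.283), but 0.973 without its 2 farthest. Scaling of the libraries was not tested as a source of the component and stays open. The TMM factors were lowest in sample 4 (0.789) and highest in sample 3 (1.17). The total count did not set these 2 samples apart. Samples 4 and 3 held 41431862 and 38808134 reads, both below the 43325210 to 48306013 of the others, yet lay at opposite ends. After TMM scaling, however, the library size was lowest in sample 4 (32677562), against 45412762 in sample 3. Detected genes were fewest in sample 4 (10152) and most in sample 3 (11975). Depth was therefore not excluded. A relation of depth with the component over all 6 libraries stays open. Its Pearson's r was 0.0988 (exact permutation p = 0.893), but 6 libraries leave an interval from -0.775 to 0.843.

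The eosinophil list had the widest range over the 6 complete libraries, though not without sample 3, 4 or 5. Its range stayed at 1.23 (log2) or more under the 3 other scalings, where the next list reached 1.09 at most. That range runs from sample 5 to sample 2, which the scalings moved nearly alike (0.08 and 0.05 by total count), so this test could hardly fail. Samples 3 and 4 were moved by 0.23 and -0.34 by total count and by -0.06 and 0.13 with DESeq2 size factors. These shifts were small next to their scores of 1.08 and -1.85, which argues against scaling as the source of that contrast. Different numbers of eosinophils in the preparations stay open and cannot be told apart from other sources: the 13 markers held by no other list moved together with a median pairwise Spearman's rho of 0.943, against 0.0286 for 1000 random lists and 0.514 at the highest, but the list was picked for its range, so that this decides nothing. The most abundant, CAT and CLC, reached 1072 and 964 CPM in sample 3, and 3 of the 18 listed genes are also in another list. The labels describe isolated neutrophils without naming a sort or gate, and expression of these genes by neutrophils themselves was not tested.

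Type I interferon genes were highest in sample 6. Scaling was argued against, since sample 6 led the next library by 1.12 (log2) or more under the 3 other scalings, and a few genes carrying the list were argued against because 25 of the 25 scored members were highest there. Monocytes, dendritic cells or lymphocytes in the preparation were argued against, since the largest excess of their marker lists in sample 6 was 0.15 (log2, dendritic cells) against 1.68 for the interferon list, while red cells, whose list was also highest in sample 6, were not tested. An interferon response of the cells themselves may lie behind the pattern, as a hypothesis found in these same data and not tested. Sample 1, with a score of 1.17 on the 19 genes it covers, was not part of these tests.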

How the results depend on the processing

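The alternatives on the genes shared with sample 1 were chosen after the data were seen. The number of genes over 2-fold, 1200, stayed within 1.5 times under the 3 other scalings (1193 to 1471). It was 501 to 888 with 1 sample left out, 557 of 7539 genes at a median of 5 CPM and 11299 of 29153 with no filter. Between the highest and lowest library it was 5522. On the shared genes it was 566 of 6281 in 6 samples and 936 of 6259 in all 7. Fewer samples, other gene sets or a wider range move such counts by construction, but not all of the change need come from that. Which sample was left out mattered, with 501 genes without sample 4 and 888 without sample 6. The share of genes over 2-fold was 7.39% at a median of 5 CPM, against 10.7% in the main setting. The number of lists at the 99th percentile, 19, was 14 to 20 under the other settings with all 6 samples, 11 to 16 with 1 left out (11 without sample 7, 12 without sample 2), 11 of 28 on the shared genes in 6 samples and 9 of 28 in all 7. The specific granule, NF-kB, immediate early and eosinophil lists were called under all 16 alternatives fixed beforehand, and the other 15 were lost under at least 1. The ratio of 26.9 between neutrophil and other-cell lists ran from 21.9 to 32.2 with 1 sample left out and was 17.0 by list means, where the erythroid list with its haemoglobin genes takes the place of the eosinophil list. Levels of 31 lists moved under list means. Relations passing the adjusted threshold numbered 0, but 1 under total-count scaling and 1 with lists scored by the median, and the cause was not tested. Detected genes numbered 11433, 12976 at 0.5 CPM and 15076 at 10 counts, which are lower limits. Of 76 genes named by their spread, 36 were over 2-fold in the main setting and fell under it in some alternative. Some of the 76 were under 2-fold already in the main setting, such as RPS19 (log2 ratio 0.57) and S100A8 (0.81). Total-count scaling moved all genes by 0.23 (log2) in sample 3 and -0.34 in sample 4, and DESeq2 size factors by 0.13 in sample 4. With 1 sample left out 0 relations passed, and the granule relation had r from 0.816 to 0.980. Leaving out sample 1 was not run, since it is in no main value. Spreads of genes, ranges of lists and levels carry no sign, so a reversal could not show in them. The correlation of the granule lists and that of the NF-kB and immediate early lists stayed positive under each alternative run. The lowest r was 0.777 (pseudocount 5) and 0.571 (without sample 2). The order of samples 6 and 7 on the NF-kB list depended on the scaling. No paired analysis was possible because the labels put the samples in no groups.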

Other observations

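The genes and counts here were chosen after the values were seen. Single libraries differed from all others by small sets of genes. Among 7201 protein-coding genes with a median of at least 5 CPM, 39 were more than 2-fold above the next library in sample 7, 18 in sample 6, 16 in sample 4, 14 in sample 3, 8 in sample 5 and 2 in sample 2. In sample 7 the widest gap was that of SLAMF7, a receptor of the SLAM family on immune cells, at 310 CPM against 16.5 CPM in the next library, 18.8-fold. It was joined by FCGR1A, the high-affinity IgG receptor, at 68.3 against 21.7 CPM, CD274 at 44.8 against 17.1 CPM and AIM2 at 39.7 against 14.6 CPM. In sample 6 the leading genes were OAS3, OAS1 (55.9 against 14.2 CPM), LY6E (76.2 against 20.9 CPM) and OAS2 (88.6 against 26.5 CPM). KRT23, a keratin, stood at 543 CPM in sample 4 against 232 CPM in the next library. Below the next library by more than 2-fold lay 135 genes in sample 4, 38 in sample 3, 28 in sample 7, 12 in sample 2, 11 in sample 5 and 3 in sample 6.

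Some abundant long non-coding RNAs varied by more than 2-fold between the lowest and highest library, namely NEAT1 (4.08-fold), MIR29B2CHG (3.90-fold) and MALAT1 (2.18-fold). The others looked at stayed under 2-fold, such as NORAD (1.60-fold), PSMB8-AS1 (1.66-fold) and FGD5-AS1 (1.76-fold). NEAT1, the scaffold of paraspeckles, ranged from 295 CPM in sample 4 and 329 CPM in sample 2 to 1205 CPM in sample 3. MALAT1 was also lowest in samples 2 (3560 CPM) and 4 (3702 CPM), and higher in samples 3 (7245 CPM) and 5 (7775 CPM). MIR29B2CHG, the host gene of a microRNA cluster, stood at 39.5 CPM in sample 2 and 45.4 CPM in sample 4 against 96.0 to 154 CPM in the others. The order of the libraries on NEAT1 was that of their share of reads outside annotated features, a relation that was not tested.

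On the genes that sample 1 covers, its granule scores were among the lowest of the 7 libraries, at -1.07 for 11 specific granule genes and -0.90 for 5 azurophil granule genes, next to -0.79 and -0.94 in sample 7. Its type II interferon score on 13 genes was 0.72, above 0.29 in sample 7. Its eosinophil score was 0.15 and its NF-kB score -0.13.

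Whether the complete libraries form separate clusters was looked at by their values and not tested. On the first component samples 2 to 7 lay at -6.77, -38.9, 47.4, -3.07, -8.90 and 10.2, and pairwise correlations over the 15 pairs ranged from 0.951 to 0.983. The highest sample differed between lists, being sample 6 for type I interferon, sample 2 for specific granules, sample 7 for immediate early genes and sample 3 for eosinophils. The leading 3 components held 41.0, 21.6 and 17.8% of the variance.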
